A study of Caenorhabditis elegans with 4 samples.

How the data were processed

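GEI-11 carrying a GFP tag was mapped by chromatin immunoprecipitation and sequencing in fed first-stage (L1) hermaphrodite larvae of Caenorhabditis elegans. Per the labels, the strain OP179 carries a bombarded transgene with the gei-11 gene fused to TY1, EGFP and 3xFLAG tags together with a rescuing copy of unc-119. Worms were fed HB101 bacteria, kept at 20 °C and fixed in 2% formaldehyde, and chromatin was collected with an antibody against GFP, per the labels' protocols. The 4 samples were 2 ChIP samples and 2 input samples, numbered as replicates 1 and 2. The labels do not say whether the replicates came from separate cultures, so any spread between them may be technical.

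The values analysed were 3 lists of binding regions, 1 for each ChIP replicate and 1 named as combined. Per the file headers, the regions were PeakSeq calls with positions in the WormBase WS220 build, carried over from an earlier build that is not named. The authors gave each region 1 measurement, a q value. No q value was 0 and none exceeded 0.01. How the replicates were combined, the aligner, the versions, the filters and the use of the inputs as controls are not given in the sources used here. The number of input lists used was 0, so no background measured in the same way stands beside the ChIP values. Sequencing depth is unknown for every sample, and a q value depends on depth, so q values rank regions within a list and do not measure occupancy across lists. Comment lines in the lists recorded 1 region of the combined list, on chromosome III, as dropped when positions were carried over, and 0 in either replicate.

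Results that place regions on genes were left out. The gene table at hand belongs to the WBcel235 assembly, positions were not moved between builds, and no genome sequence of WS220 was used. Binding at gene classes, annotation of regions, sequence motifs and the gei-11 and unc-119 loci were therefore planned and are not analysed here. From that table only gene names and the chromosome of each gene were taken. Regions are named by WS220 position, counted from 1, and what is annotated at each position is not analysed here.

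Regions of different lists were matched when they shared at least 1 bp. Replicate overlap was tested one-sided against 1000 random placements of the other replicate's regions within their chromosomes, with 100 placements for the alternatives based on 50% of the shorter region and on centres within 200 bp. The q values of matched regions were correlated as −log10 q with Pearson's r and Spearman's rho, with 100000 permutations of the pairings, two-sided. Regions per chromosome were compared with chromosome length by two-sided exact binomial tests, adjusted by the Benjamini-Hochberg method over 6 chromosomes, with 0.05 as the threshold. Chromosome length was taken as the furthest region end in any list, 100194792 bp in all. On chromosome IV, region centres were counted from 4.5 to 7 Mb and from 14 to 17 Mb, called the domains below. These are rounded borders for the broad domains that hold the 21U-RNA (piRNA) genes, and gene positions were not used to set them. The counts were tested by an exact binomial test and by 1000 circular shifts along the chromosome, one-sided. Arms were the outer parts when each chromosome was divided into 3 equal lengths, tested over 5 autosomes. Binomial tests count regions as independent although neighbouring regions cluster, so blocks of 1 Mb were also permuted, an alternative chosen after seeing the data. Differences between arm and centre blocks were tested over all splits of the blocks of a chromosome, an exact permutation test, adjusted over 5 autosomes and, for chromosome X, over all 6 chromosomes. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only.

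Named regions followed a rule set before the data were examined: the 20 combined regions with the smallest q value that met a region in both replicates, and the 5 windows of 100 kb with most combined regions, ties broken by position. The parts of the rule that need gene positions were not used. Regions named outside this rule were chosen after their values were seen, and the text says so. Alternatives changed the overlap needed, the strength of the regions kept, the list, the merging of neighbours, the borders of the domains and arms and the unit of the test.

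The statistics were tested on simulated data, 100 lists of 5999 regions per setting. In the 1.3-fold setting, 100% of lists had the chromosome called, 86% the chromosome IV domains and 81% the arms. In the 2-fold setting, 100% of lists were called in each case. For the domains and arms the fold was a weight in drawing regions without replacement, so the excess reached there was smaller than the fold. As a ratio to length share, the simulated domain excess averaged 1.15 in the 1.3-fold setting and 1.38 in the 2-fold setting. With no excess, 1% of lists had the chromosome called, 6% the domains and 1% the arms. Simulated regions were placed independently while the real regions cluster, so these rates need not hold for the binomial tests on the real lists. In 5 simulated lists with a true overlap of 60.4%, the recovered overlap exceeded the true one by 0.787 percentage points. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.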

Results

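GEI-11, also known as SNPC-4, is a subunit of the SNAPc complex, which directs transcription of small nuclear RNA genes. The gene table lists it as snpc-4, sequence name F32H2.1, on chromosome I. Its GFP fusion was mapped in fed L1 larvae in 2 ChIP replicates, each with an input. The replicate 1 list held 3021 regions, the replicate 2 list 3722 and the combined list 5999. Regions were narrow, with median widths of 313 bp, 308 bp and 315 bp. They covered 1070 kb in replicate 1, 1278 kb in replicate 2 and 2119 kb in the combined list, the last being 2.11% of the genome length. Median −log10 q was 3.53 in replicate 1, 3.72 in replicate 2 and 4.20 in the combined list. A q value of 1e-10 or less was reached by 346, 528 and 1181 regions. Regions narrower than 50 bp numbered 104, 144 and 438. No read depth or input signal was analysed, and each list is a single measurement.

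The first comparison asked whether GEI-11 sites of one replicate were called again in the other. In replicate 1, 2344 of 3021 regions (77.6%, 95% interval 76.1 to 79.1) met a region of replicate 2, where random placement gave 2.63% on average and 3.71% at most. In replicate 2, 2343 of 3722 regions (63.0%, interval 61.4 to 64.5) met a region of replicate 1, against 2.12% by chance. Both shares exceeded all 1000 placements, at a one-sided permutation p of 0.001, the smallest these placements can give. Beyond the very strongest regions, repeated calling followed strength. Of the first 100 replicate 1 regions by q value 98 were met, and the 2 unmet ones held ranks 1 and 2. Of those ranked 101 to 500 all 400 were met, and 490 of the 500 regions ranked 501 to 1000 were met. The share was 81.0% at ranks 1001 to 2000 and 53.5% beyond. In replicate 2 the corresponding numbers were 100 of 100, 399 of 400, 477 of 500, 75.4% and 35.6%. Met regions of replicate 1 had a median −log10 q of 4.23 and a median width of 333 bp, against 2.40 and 222 bp for the others. In replicate 2 these values were 5.39 and 341 bp against 2.56 and 236 bp. The difference in mean −log10 q had a permutation p of 0.0001 in each replicate, the smallest that 10000 permutations can give.

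The q values of the 2344 matched regions rose together in the replicates, with a Pearson r of 0.974 and a Spearman rho of 0.730 on the −log10 scale. Each permutation p was 1e-05, the smallest that 100000 permutations can give. The correlation runs across regions of one pair of libraries, and regions are not independent replicates. Replicate 2 had the higher −log10 q in 1676 pairs (71.5%), with a median difference of 1.06 (replicate 2 minus replicate 1). Depth is unknown, so this difference does not measure occupancy.

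**Figure D1:**
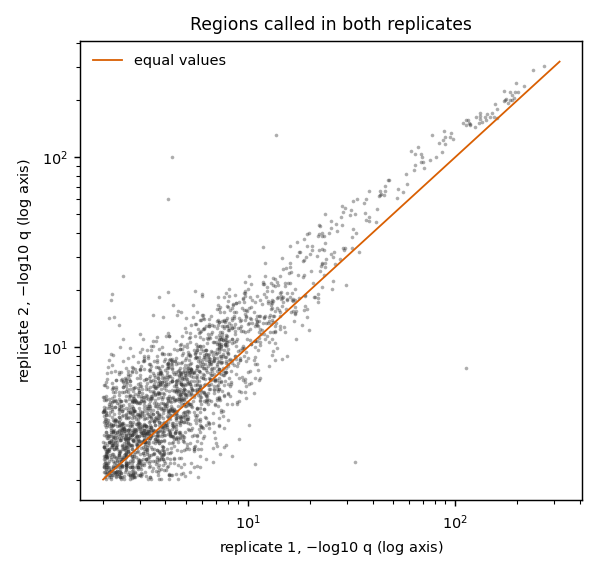
Each point is a replicate 1 region and the replicate 2 region it overlaps most, with −log10 q of replicate 1 on the x axis and of replicate 2 on the y axis, both log axes. Most points, 71.5% of 2344, lie above the line of equal values.

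Of the 5999 combined regions, 2325 (38.8%, interval 37.5 to 40.0) met a region in both replicates, 489 (8.15%) in replicate 1 only and 1192 (19.9%) in replicate 2 only. The remaining 1993 (33.2%, interval 32.0 to 34.4) met none. Combined regions found in both replicates had a median −log10 q of 10.1 and a median width of 406 bp. Those found in neither had 2.48 and 197 bp. All 500 of the strongest combined regions were found in both replicates. At ranks 2001 to 3000 the share was 42.7%, and at ranks 4001 to 5000 it was 0%, with 68.6% found in neither. In the other direction, 2856 replicate 1 regions (94.5%) and 3559 replicate 2 regions (95.6%) met a combined region. The 165 and 163 unmet ones lay below rank 500 in their list, except for 5 of the 10 strongest regions of replicate 1 and 3 of the 10 strongest of replicate 2.

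**Figure D2:**
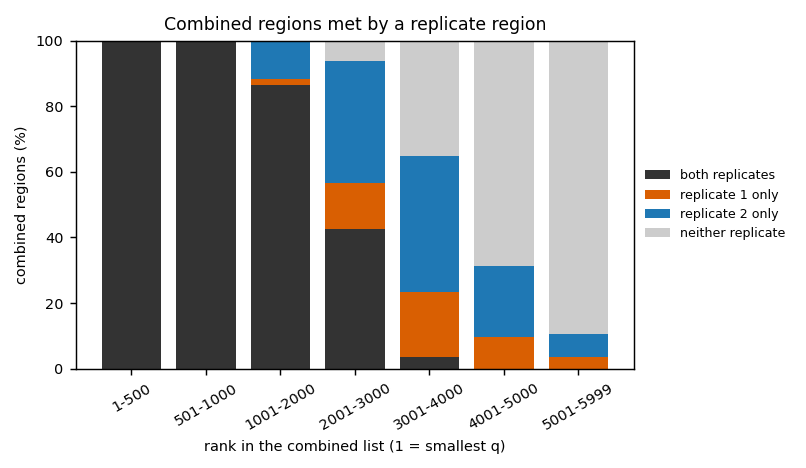
Bars show the percentage of combined regions, grouped by rank of q value, that met a region in both replicates, in 1 of them or in neither. Support by both replicates runs from 100% in the strongest 500 regions to 0% from rank 4001 on.

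Of the 20 named regions, the strongest of the combined list that both replicates shared, 6 were on chromosome I, 5 on II, 4 on III, 3 on IV, 2 on V and 0 on X. Among the strongest regions of both replicates, 3 could not enter the 20, since the combined list used here lacks them. Chromosome II 13834206 to 13835242 ranked 3 in replicate 1 and 1 in replicate 2. Chromosome IV 9510413 to 9512138 ranked 4 and 2, and chromosome X 14476431 to 14477829 ranked 7 and 3. These 3 were chosen after their values were seen. Widths of the 20 named regions ran from 763 to 1961 bp, and −log10 q was higher in replicate 2 than in replicate 1 for all 20. The smallest combined q value, 4.54e-286, belonged to chromosome III 11090082 to 11091142, with −log10 q of 172 in replicate 1 and 224 in replicate 2. Next came chromosome III 5080419 to 5081496 (q 1.08e-266) and chromosome III 10989144 to 10990057 (q 2.30e-254). Chromosome I held the following regions, 13463452 to 13464397 (q 9.25e-254) and 2084242 to 2085774 (q 1.20e-247). The strongest named region of chromosome II was 12944409 to 12945444 (q 1.42e-243), of chromosome IV 9444068 to 9444995 (q 1.49e-214) and of chromosome V 8499813 to 8500799 (q 1.47e-205). A region near the left end of chromosome I, 3523 to 4923, had a q of 2.12e-199. Over the 20, −log10 q ran from 88.4 to 215 in replicate 1 and from 138 to 237 in replicate 2, with the lowest value of each at chromosome II 13829004 to 13830572.

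The window with most combined regions, chromosome III 7100001 to 7200000, held 20, with 13 in replicate 1 and 15 in replicate 2. Windows on chromosome II from 6800001 and from 10500001 and on chromosome III from 5600001 held 18 each. The fifth, chromosome I from 10500001, held 17 and was 1 of 4 windows with that number. Random placement gave a highest window of 16.1 regions on average and 22 at most, with a permutation p of 0.0200 for 20. Over 1005 windows of 100 kb, 67 held 12 or more regions, against 25 on average and 39 at most in 1000 random placements. Empty windows numbered 16, against 4.84 on average and 14 at most. Permutation p was 0.001 for each of these counts, the smallest possible there.

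The regions were unevenly shared among chromosomes. Chromosome III held 1036 combined regions, 1.26 times the number expected from its length (interval 1.19 to 1.33, adjusted p = 9.62e-14 in an exact binomial test). Chromosome V held 1099, at 0.878 times (0.832 to 0.926, exact binomial adjusted p = 2.72e-06). By the same exact test, chromosome II lay at 1.08 times (1.02 to 1.14, adjusted p = 0.0226) and chromosome X at 0.935 times (0.882 to 0.990, adjusted p = 0.0292). Chromosome IV, at 0.992 times (0.938 to 1.05), did not pass the exact test (adjusted p = 0.799), nor did chromosome I, at 0.941 times (0.883 to 1.0, adjusted p = 0.0667). Chromosome I lay lower in the replicates, at 0.671 times in replicate 1 (0.601 to 0.746) and 0.731 times in replicate 2 (0.665 to 0.80). With blocks of 1 Mb as the unit, chromosome III had 75 ± 17.3 regions per Mb (SD, 13 blocks) against 57.6 elsewhere (adjusted permutation p = 0.00240). Chromosome V had 51.8 ± 10.5 (SD, 20 blocks) against 62.0 elsewhere (adjusted permutation p = 0.0373). The calls for chromosomes II and X ended in this test, with adjusted permutation p of 0.463 and 0.480. In replicate 2 alone chromosome X was not called (0.960 times, exact binomial adjusted p = 0.264), and in replicate 1 alone chromosome IV was, at 1.08 times (exact binomial adjusted p = 0.0416). Each ratio is a share of all regions of its list, so the low count on chromosome I in the replicates raises the ratios of the other chromosomes there.

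**Figure D3:**
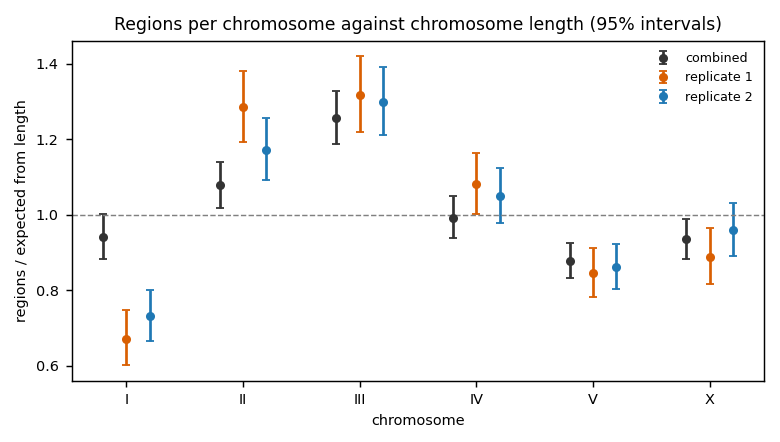
Points show the number of regions per chromosome divided by the number expected from its length, for each list, and bars are 95% exact intervals. Chromosome III lies above 1 and chromosome V below 1 in all 3 lists, and chromosome I is lower in the replicates (0.671 and 0.731) than in the combined list (0.941).

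Chromosome IV carries the 21U-RNA (piRNA) genes in 2 broad domains, and the next comparison asked whether GEI-11 regions were denser there. Of 1039 combined regions on chromosome IV, 339 (32.6%) had their centre in the domains, which make up 31.5% of the length. The ratio was 1.04 (interval 0.947 to 1.13) and did not pass the test (exact binomial p = 0.423, one-sided circular shift p = 0.262). The domain from 4.5 to 7 Mb had a ratio of 1.0 and the domain from 14 to 17 Mb a ratio of 1.07 (0.931 to 1.21). Replicate 1 gave 0.959 (0.840 to 1.08) and replicate 2 gave 1.04 (0.928 to 1.16). Regions inside the domains had a median width of 275 bp and a median −log10 q of 3.76, against 310 bp and 4.19 outside. In replicate 1 the median −log10 q ran the other way, 3.44 inside and 3.16 outside, and in replicate 2 it was 3.54 and 3.68; these differences were not tested. Wider borders, 4 to 8 and 13 to 17 Mb, gave 1.06 with a one-sided circular shift p of 0.0350 and an exact binomial p of 0.0989. Counts of regions do not measure the broad signal between regions, which was not analysed here. The result covers fed L1 larvae only, and no other stage or single tissue was sampled.

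Arms and centres of the chromosomes were compared next, since gene content differs between them in this species. On chromosome V, 683 of 1099 regions lay in the arms, 0.932 times the number expected from length (0.888 to 0.975, exact binomial adjusted p = 0.00852). Arms had 47.6 ± 7.77 regions per Mb (SD, 13 blocks) and the centre 59.6 ± 11 (SD, 7 blocks). With blocks as the unit this call ended, with an adjusted exact permutation p over the 5 autosomes of 0.0623 in the combined list, 0.0691 in replicate 1 and 0.116 in replicate 2. Adjusted over all 6 chromosomes, with X included, the combined list passed (exact permutation adjusted p = 0.0451) and the replicates did not (0.0810 and 0.0697). The arms of chromosomes II and III lay at 0.947 (adjusted p = 0.0329) and 0.940 times (adjusted p = 0.0171) in exact binomial tests. Both of these calls also ended with blocks as the unit and in each replicate list alone. Arms of chromosomes I and IV, at 0.973 and 1.0 times, did not pass the exact binomial test (adjusted p = 0.344 and 1). On chromosome II the left arm held 238 regions and the right arm 384, values not tested against each other.

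**Figure D4:**
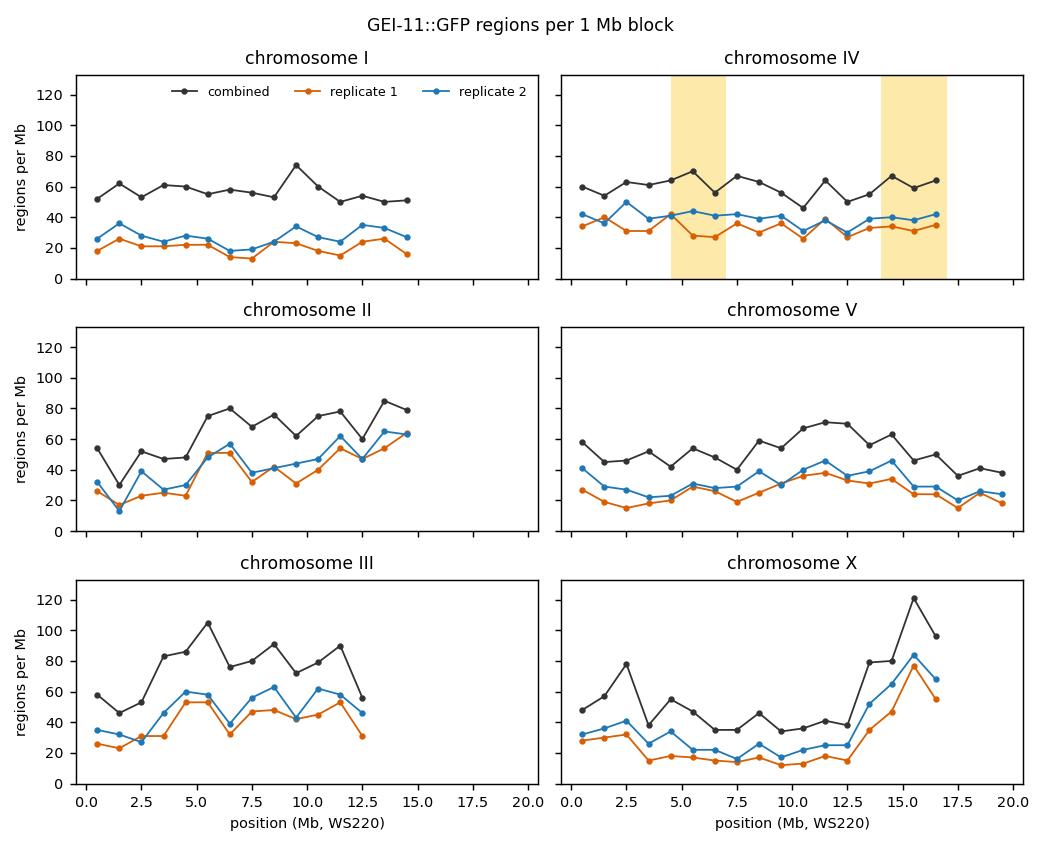
Lines show the number of regions in each full 1 Mb block along the 6 chromosomes, in WS220 positions, for the combined list and each replicate, and shading on chromosome IV marks the piRNA domains. The highest block, on the right arm of chromosome X, holds 121 combined regions.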

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

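The tests on 1 Mb blocks, on regions of at least 50 bp, with unmatched replicate regions added and on the arms of chromosome X were chosen only after the data were seen. No paired analysis was possible because the inputs that share replicate numbers with the ChIP samples have no region list here, so no fit over the 4 samples exists. Of 142 alternatives, 92 were counted as unchanged and 7 moved a share beyond its interval. Unchanged means the same direction and side of the threshold, or a value within its interval. The 92 also include counts of regions per list, which carry no test or interval. They include the overlap and correlation alternatives, where every permutation p was the smallest possible, so these could hardly change. Calls were lost in 20 and gained in 5. The direction turned in 20, of which 1 also lost a call, 1 gained one and 18 did neither. Replicate overlap kept its call in every alternative run, from 74.7% to 82.9% for replicate 1 and from 60.7% to 78.8% for replicate 2, and rho ran from 0.730 to 0.756. The excess of regions on chromosome III and the deficit on chromosome V also kept theirs in the alternatives run. Among regions of q 1e-10 or less, a set examined beside these, chromosome V did not pass (0.913, 0.873 and 0.826 times in the combined list and replicates 1 and 2, exact binomial adjusted p = 0.199, 0.348 and 0.0626). Chromosome III passed in the combined list (1.23 times, exact binomial adjusted p = 0.00799) and replicate 2 (1.3, 0.0188) and not in replicate 1 (1.3, 0.0570). Chromosome II passed in each list of this set, at 1.25, 1.46 and 1.28 times in the combined list and replicates 1 and 2. Its exact binomial adjusted p was 0.00251, 0.00164 and 0.0188. This set was not tested over blocks, and the chromosome II call over all combined regions ended in the block test. Unless stated, the cause of a change was not tested.

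With 1 replicate list alone, the ratio to length ran from 0.671 to 0.731 on chromosome I, 1.17 to 1.29 on II, 1.3 to 1.32 on III, 1.05 to 1.08 on IV, 0.846 to 0.863 on V and 0.888 to 0.960 on X, and from 0.959 to 1.04 in the piRNA domains. Arm ratios ran from 1.02 to 1.05 on I, 0.973 to 0.986 on II, 0.954 to 0.959 on III, 0.992 to 1.01 on IV, 0.903 to 0.925 on V and 1.2 to 1.22 on X. Combined regions found in both replicates gave 0.712 on chromosome I, 1.03 on IV, 0.932 on X and 0.996 in the piRNA domains, and arm ratios of 1.04 on I, 1.02 on II, 0.961 on III and 0.983 on IV. The stronger 50% of regions gave support by both replicates of 41.3% and by neither of 31.1%, a piRNA domain ratio of 0.975, and arm ratios of 1.01 on I, 0.993 on II, 0.971 on III and 0.986 on IV. The strongest 500 of each list gave 76.6% and 3.20%. Centres within 200 bp gave 36.7% in both. Merging regions within 1 kb gave 1.05 on chromosome II, 1.0 on IV and 0.960 on X, and arm ratios of 0.952 on II and 0.991 on IV. Narrower arms, the outermost of 4 equal parts, gave an arm ratio of 0.934 on II. Covered length gave 0.930 in the piRNA domains. Domain borders of 4 to 8 and 13 to 17 Mb gave 1.06, with an exact binomial p of 0.0989 and a one-sided circular shift p of 0.0350, the lowest shift p over the alternatives.

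Regions of at least 50 bp gave 41.4% in both and 29.8% in neither, 0.955 on chromosome X and 0.999 for the arms of IV. Adding unmatched replicate regions gave 0.906 on chromosome I and 1.03 on IV. Blocks of 1 Mb gave ratios of 1.09 on II, 1.0 on IV and 0.936 on X, and arm ratios of 0.941 on II, 0.923 on III and 0.919 on V (adjusted exact permutation p = 0.0623 over 5 autosomes and 0.0451 over 6 chromosomes), and they leave fewer units to test. The alternatives set out for gene class binding, region annotation and sequence motifs were not run, for want of an annotation and sequence of the same build. Depth is unknown, so the limit it sets on weak regions was not measured.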

Other observations

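Among the tests below, several were chosen only after the results were seen. These were the tests on chromosome X, on gene classes, on the missing strong regions, on regions found in neither replicate and on matched q values. Covered length was an alternative set before the data were examined, and its use against wide regions was decided after. The tests of strong regions on chromosome I and in the piRNA domains were set before their results were seen.

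As a share of the GEI-11 regions of chromosome X, its right arm was in excess. The right arm held 447 of 991 combined regions (45.1%, interval 42.0 to 48.3) on 1 of 3 equal parts of the length (33.3%), with an adjusted exact binomial p of 3.04e-14, and the left arm 319 (32.2%, 29.3 to 35.2, adjusted p = 0.459). In the replicates the right arm held 52.1% and 49.9% and the left 29.3% and 30.1%. The right arm alone was not tested over blocks, and the binomial test counts clustered regions as independent. Both arms together held 766 regions, 1.16 times the number expected from length (interval 1.12 to 1.2, exact binomial p = 2.65e-13). Arms had 67.0 ± 26.2 regions per Mb (SD, 11 blocks) and the centre 37.8 ± 4.71 (SD, 6 blocks), with an adjusted exact permutation p of 0.0451 over 6 chromosomes. Replicates 1 and 2 gave ratios of 1.22 and 1.2, with adjusted exact permutation p of 0.0810 and 0.0697 over blocks. Blocks of the other chromosomes held 60.6 combined regions on average, so the centre of X lay below them. Shares within X depend on each other, so a low centre and dense arms are not separated by these tests. The last 4 full blocks, from 13 Mb on, held 79, 80, 121 and 96 combined regions. These blocks are neighbours, while the block test treats each block as independent of its neighbours. Chromosome X had 0 of the 20 named regions. Its region 14476431 to 14477829, ranked 7 in replicate 1 and 3 in replicate 2, could not enter them because the combined list used here lacks it.

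Some small RNA gene classes are crowded on 1 chromosome. In the WBcel235 gene table, 276 of 612 tRNA genes (45.1%) lie on chromosome X and 14714 of 15363 21U-RNA genes (95.8%) on chromosome IV, while 16.5% of combined regions lay on X and 17.3% on IV. The number of regions per chromosome was correlated with the number of genes of 8 classes over 6 chromosomes, neither scaled by length, and none passed an exact permutation test. The lowest adjusted p was 0.476 for Pearson's r and 0.644 for Spearman's rho. For tRNA genes r was -0.0113 (p = 0.978, adjusted p = 0.978) and rho 0.429 (p = 0.419, adjusted p = 0.644), and without the 2 farthest chromosomes r was 0.603. In the same way r went from 0.515 to -0.366 for snRNA genes, from -0.450 to -0.802 for snoRNA genes and from 0.685 to 0.267 for histone genes. It went from 0.231 to 0.0518 for 21U-RNA, from -0.0853 to 0.0347 for miRNA, from 0.569 to 0.445 for protein-coding and from -0.499 to -0.369 for ribosomal protein genes. For 21U-RNA and tRNA genes, crowded on 1 chromosome, r rests largely on the region count of that chromosome. Such a test could hardly pass over 6 chromosomes, and chromosome length is not removed. No conclusion on binding at these genes follows from it. The widest combined region, chromosome III 9050876 to 9054896, spanned 4021 bp with a q of 5.94e-69 and was found in both replicates. It was chosen after its values were seen.

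Among the strongest replicate regions, 5 had no overlapping counterpart in the combined list used here, though other combined regions lay near 4 of them, and they are named because of that. Chromosome II 13834206 to 13835242, chromosome IV 9510413 to 9512138 and chromosome X 14476431 to 14477829 were in both replicates, with replicate 2 q values of 1.60e-303, 1.35e-290 and 1.05e-246 and the nearest combined region 571, 330 and 226 bp away, so 3 of the 5 had a counterpart among the 10 strongest of replicate 2 and a signal in 1 replicate only cannot cover all 5, while chromosome II 5543228 to 5544528 (3.86e-293) and 14804070 to 14804906 (3.36e-274, nearest combined region 1244 bp away) were in replicate 1 alone. The number of these named in a comment line as dropped when positions were carried over was 0, which argues against loss in that step as far as the comments record it. A q value too small for a double-precision number may have removed some of them. A regression on 63 regions (residual SD 12.2) predicted combined −log10 q of 327 and 314 for the first and second. For the third it predicted 271, below the 285 of the strongest combined region. The first 2 predictions lie beyond 308, the limit of full precision. Smaller numbers can still be held at reduced precision, so passing that limit does not by itself mean a loss, and this stays open for these 2. The third prediction does not reach that limit, so a loss of this kind is not predicted for that region. For the 2 regions of replicate 1 alone, a fit on replicate 1 predicted replicate 2 values of 319 and 300.4 (residual SD 12.1), within reach of that limit. The lower prediction lies below the 302.8 that replicate 2 kept for its strongest region, so a value of that size was not lost there. The same loss may apply, less clearly for the lower prediction, and a signal in 1 replicate stays open for both regions. A filter, or lists that are incomplete as used here, was not tested and would also bear on the counts and the 20 named regions. No biological explanation was tested.

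Chromosome I had fewer regions in the replicates than the combined list would give. Combined regions found in neither replicate made up 399 of 849 (47.0%) on chromosome I and 1594 of 5150 (31.0%) elsewhere. Fisher's exact test gave p = 2.56e-19 and restates the lower replicate counts that prompted it. At matched q value the odds of being found were 0.120 times those elsewhere (0.0878 to 0.165). For the other chromosomes they were 1.1 to 1.60, each set against a remainder that holds chromosome I. The intervals for III (0.998 to 1.54) and V (0.892 to 1.36) include 1. Few strong sites on chromosome I were tested first by the ratio at q of 1e-10 or less. It was 0.906 (0.780 to 1.05) in the combined list, which by itself left the question open. The replicate lists gave 0.577 (0.394 to 0.808, exact binomial adjusted p = 0.00164) and 0.718 (0.551 to 0.915, exact binomial adjusted p = 0.0188). A second comparison, added after that outcome, used the same groups of q value as the odds ratio. It restates that ratio and is not separate evidence. By it, 53.0% of chromosome I regions were found (49.6 to 56.4) against 70.8% from the rates elsewhere at the same q. The matched values argue against few strong sites as the whole cause, provided the combined q value measures strength alike on all chromosomes. Among regions of q 1e-10 or less found in both, replicate 1 −log10 q was at the median 33.5% of the combined value on chromosome I and 42.7% elsewhere, and in replicate 2 it was 47.7% and 57.3% (permutation p = 0.0001 for the mean difference in each, the smallest that 10000 permutations can give). A weaker signal or a stricter call on chromosome I in the single replicates may therefore lie behind the pattern, and these lists do not separate the pair. The odds and the percentages of the combined value are set against the combined q value, and how the combined list was made is not known. A difference on chromosome I in the combined list could give the same values, so the replicate side and the combined side are not separated either. No biological explanation was tested.

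In these L1 larvae, the piRNA domains of chromosome IV showed no excess of regions that passed the test within the borders set. Wider borders gave 1.06 with a one-sided shift p of 0.0350 and an exact binomial p of 0.0989. Counting wide regions once could hide one, but covered length gave a ratio of 0.930, which argues against that. Weak regions could hide an excess of strong ones: regions of q 1e-10 or less gave a ratio of 1.11 (0.895 to 1.34, exact binomial p = 0.309), an interval that holds both no excess and a moderate one, so this cannot be told apart here. No biological explanation was tested.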
